A study of Mus musculus with 4 samples.

How the data were processed

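By the labels, RNA was measured in Neuro2a (N2a) cells, a mouse neuroblastoma line. The cells were transfected with a scramble siRNA or with an siRNA against Men1, the gene that encodes menin. The labels give 4 single-colour arrays, 2 per group, each numbered as replicate 1 or 2. Nothing in the labels says that replicates came from separate cultures, so p-values here measure only the spread between these arrays, which may be technical. An exact permutation test of 2 arrays against 2 cannot give a two-sided p below 0.33, so every test used a model fitted across all genes.

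Per the file headers, each array held 44170 targets besides 1 control row of 5000 random probes, which was left out. Of the targets, 44155 had 3 probes and 15 had 1 or 2. The deposited values are intensities on a linear scale, summarised per target by the robust multi-array average (RMA) per the file headers. Scanner software and background correction are not given in the sources used here. The series text names an Agilent array, whereas the labelling protocol in the labels and the format of the files are those of a NimbleGen array, and the files were treated as NimbleGen. Array medians were 146.0 and 151.2 for the scramble siRNA arrays and 145.9 and 147.2 for the Men1 siRNA arrays. The random probes read 45.5, 42.8, 48.1 and 52.3 on the same arrays in that order. No array file marks which targets are above background. An intensity of 100 was taken as the level well above background, because the authors' value table of the series holds exactly the 20620 targets that reached 100 on all 4 arrays. Between 40.2% and 41.0% of targets lay under 100 on each array.

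The value table was set against the per-array files, with values counted as equal within a relative tolerance of 1e-04. It is on the same linear scale and is not centred. Its column medians were 684.7 and 637.6 for scramble siRNA replicates 1 and 2, and 667.6 and 635.1 for Men1 siRNA replicates 1 and 2. For 20617 of the 20620 targets the values equalled those of arrays of the same group, with the 2 scramble siRNA columns holding each other's values. The other 3 targets are all 3 targets of Cdk5r1, and their entries in the value table equal the per-array values of the other group. The per-array files were used throughout, and the value table only as an alternative.

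Gene symbols came from the array annotation, placed on mouse build MM9, and were updated through NCBI gene IDs. Of 24204 gene IDs, 21583 matched a current symbol, of which 3302 changed, and 2621 kept the symbol of the file. Values were taken to log2 with no pseudocount and no further normalization. For the 10216 genes with more than 1 target, the target with the highest mean log2 value over the 4 arrays stood for the gene, which left 24171 genes after targets without a symbol were set aside. Differences were tested with lmFit and eBayes of limma 3.58.1 in R 4.3.3, with group as the only term, default prior and two-sided p-values, adjusted by the Benjamini-Hochberg method with a threshold of 0.05. Log2 changes are Men1 siRNA minus scramble siRNA, with the moderated standard error (SE). Where both arrays of a group lay under 100, the fold is given as "at least": the mean of the brighter group against 100 or the dimmer group's own value, whichever was higher on each array. Where 1 array of a group lay under 100, the fitted change is given, and its size is less certain. Coordinates are those of the files on MM9. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the files and drew the plots.

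The design, the alternatives, the 28 gene lists and the rule for named genes were fixed before the data were examined. The rule names Men1, and Cdk5r1, which a paper on menin in neurons concerns. It names the 12 largest increases and 12 largest decreases among genes past the threshold whose arrays do not overlap and whose higher group has a mean log2 value above the median of all genes, 7.54. Clone names and predicted genes are only counted. Free places go to the smallest unadjusted p among genes with an absolute log2 change of at least 1, and up to 4 members with the smallest p are named per list; some genes that the rule would name are not reported here. Lists were tested with camera at its preset correlation of 0.01, with an estimated correlation and with fry, all from limma, adjusted over the 28 lists. Counts of members past the threshold are given adjusted over all genes and adjusted over the list alone.

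The test was tried on simulated data for the comparison of Men1 siRNA with scramble siRNA, on 24171 genes in 5 runs with 200 genes changed per run. It recovered 0% of genes changed by 1 log2 unit, 3.2% of those changed by 2, 73.6% of those changed by 4 and 95.6% of those changed by 6. Of 454 simulated calls, 23 were of unchanged genes. Camera found 25 of 25 lists moved by 1 log2 unit and called 0 of 115 unmoved lists, with the same lists moved in every run. Simulated genes varied independently of each other, so these counts do not test camera where list members vary together. The number of arrays limits the precision, and at this size a change of 2 log2 units or less is mostly missed.

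Alternatives were the replicate number as a block, each array left out in turn, cyclic loess, median and quantile normalization, and the value table. Others were a filter on dim genes, the mean of all targets, each target alone, a trended or robust prior, a pseudocount of 32, an added change of 1 log2 unit and an adjusted p under 0.01. A block with crossed replicate numbers and a floor at an intensity of 100 were added after the data were seen. Marker lists of whole tissues in the closing section were also written after a first look at the leading genes.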

Results

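Gene expression was measured on 4 arrays labelled as Neuro2a (N2a) mouse neuroblastoma cells. By the labels, 2 were of cells transfected with scramble siRNA and 2 of cells transfected with an siRNA against Men1. Forebrain, globin and epithelial transcripts on these arrays, given in the closing section, leave open whether the RNA came from N2a cells alone. Men1 encodes menin, a scaffold protein of a histone H3 lysine 4 methyltransferase complex. The arrays of a group correlated with r = 0.948 (scramble siRNA) and r = 0.945 (Men1 siRNA) across targets, and arrays of different groups with r between 0.901 and 0.934. Targets are not independent replicates. The design asks which transcripts differ when Men1 is knocked down.

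Men1 (gene ID 17283, chromosome 19, 6335113 to 6340885 on MM9) was the targeted gene. Its brighter target read 6985 and 6222 on the scramble siRNA arrays and 2764 and 4109 on the Men1 siRNA arrays, 0.511 times the scramble level. The log2 change was −0.97 ± 0.35 (SE, n = 2 arrays per group), which did not pass the threshold in limma (adjusted p = 0.314). The other Men1 target gave −0.19 ± 0.33, with 3843 and 3824 against 2989 and 3802. Both Men1 siRNA arrays lay below both scramble siRNA arrays at each target, so the values have the direction of the labels without passing the test.

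Cdk5r1 (gene ID 12569, chromosome 11, 80290555 to 80294035 on MM9) encodes p35, the neuronal activator of the kinase Cdk5. In the per-array files it read 12725 and 14798 with scramble siRNA and 20604 and 22773 with Men1 siRNA, a log2 change of 0.66 ± 0.31 (SE, n = 2 per group; limma adjusted p = 0.414). All 3 Cdk5r1 targets were positive, from 0.59 to 0.66, and none passed. The series' value table gives this gene in the opposite direction: its 4 values for the same target are 20604 and 22773 under scramble siRNA and 14798 and 12725 under Men1 siRNA, a log2 change of −0.66. The 3 targets of Cdk5r1 are the only ones of 20620 in that table whose values belong to the other group's arrays in the per-array files. The direction of Cdk5r1 therefore depends on which deposited source is read.

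**Figure D1:**
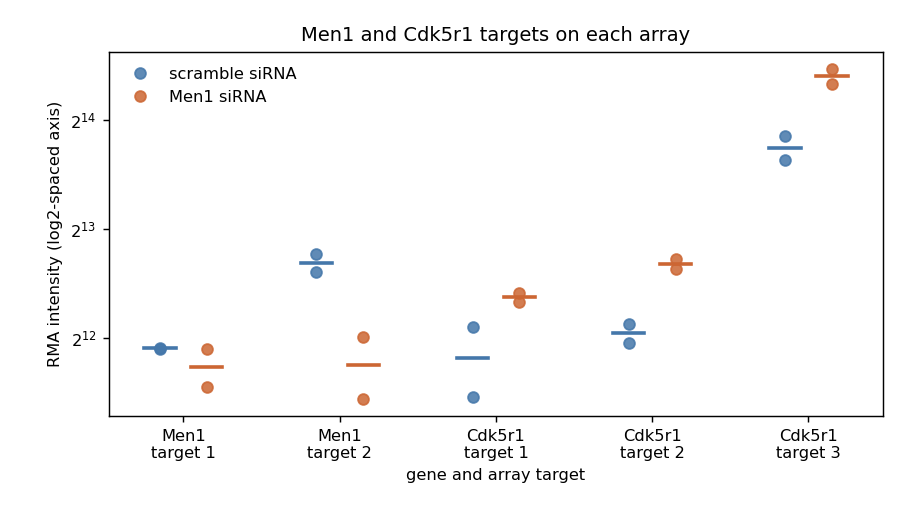
Intensity (log2-spaced axis) of the 2 Men1 and 3 Cdk5r1 targets on each array in the per-array files; points are single arrays and short lines the arithmetic mean of 2 arrays. Men1 target 2 has a log2 change of −0.97, and the 3 Cdk5r1 targets lie between 0.59 and 0.66, with signs opposite to those of the value table.

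Of 24171 genes, 94 passed the threshold in limma, 9 higher and 85 lower with Men1 siRNA. The genes that fell include collagens, epithelial genes and developmental transcription factors. Sprr2f, a cornified envelope protein gene of epithelia, fell from 18940 ± 6873 to 131.7 ± 83.4 (mean ± SD, n = 2), by 7.28 ± 0.56 (SE) on the log2 scale. Col6a2, a chain of type VI collagen, fell by 5.75 ± 0.34, from 14000 to 255.8, at the brightest of its 3 targets. The other 2 had −2.04 and −1.01, and their mean with it was −2.93 without passing (adjusted p = 0.0679). Hdc, which encodes histidine decarboxylase, fell by 6.23 ± 0.66, with 14235 and 4306 on the scramble siRNA arrays. Msx1, a homeobox gene, fell by 5.53 ± 0.46, and Cbr2, a carbonyl reductase gene, fell by 5.26 ± 0.58. The size of some of these falls is uncertain, because the lower Men1 siRNA array was under 100. It read 72.8 for Sprr2f, 75.6 for Hdc, 74.8 for Msx1 and 67.6 for Cbr2. Limma's adjusted p-values were 0.0327 for Sprr2f, 0.0275 for Col6a2, 0.0405 for Hdc, 0.0346 for Msx1 and 0.0423 for Cbr2.

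For 7 of the 12 largest decreases both Men1 siRNA arrays were under 100, so only a bound on the fold can be given. Gata2, a zinc finger transcription factor gene, was at least 45.5-fold lower, with a mean of 4727 ± 1803 (SD, n = 2) on the scramble siRNA arrays and 83.7 ± 0.26 on the Men1 siRNA arrays. Plekhs1 was at least 40.1-fold lower, Slc39a4, a zinc importer gene, at least 35.1-fold, and the homeobox gene Hoxa11 at least 30-fold. Fads2b was at least 23.8-fold lower, Fxyd4, a regulator of the sodium pump, at least 20.6-fold, and the tight junction gene Cldn3 at least 16.8-fold. Fxyd4 rests on 1 of its 2 targets. The other had −0.60, and the gene had −0.25 without scramble siRNA replicate 1 (adjusted p = 0.895), −0.96 without scramble siRNA replicate 2, −0.60 in the value table and −3.06 as the mean of its targets. Limma's adjusted p was 0.0281 for Gata2, 0.0275 for Slc39a4 and Hoxa11, 0.0327 for Plekhs1 and Fads2b, 0.0346 for Fxyd4 and 0.0405 for Cldn3. Of all 85 genes that fell, 38 had both Men1 siRNA arrays under 100. The Sprr2 genes are near-identical paralogs and may share probes, so the value of Sprr2f is uncertain.

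Among the genes that rose, Fabp4, the fatty acid binding protein of adipocytes, went from 97.2 ± 14.1 to 2618 ± 519 (mean ± SD, n = 2), a log2 change of 4.74 ± 0.34 (SE), with 1.72 at its other target. Car3, a carbonic anhydrase gene abundant in fat and muscle, rose by 4.48 ± 0.43, from 92.6 to 1989, with 1.52 at its other target. Ankrd1, a nuclear ankyrin repeat gene known from heart muscle, was at least 49.9-fold higher, with 76.4 and 78.1 on the scramble siRNA arrays and 3888 and 6396 on the Men1 siRNA arrays. Msln was at least 7.06-fold higher, Map3k7cl at least 3.77-fold and Cyp4a12a at least 7.05-fold. Limma's adjusted p was 0.0281 for Fabp4, 0.0364 for Car3, 0.0275 for Ankrd1, 0.0408 for Msln, 0.0442 for Map3k7cl and 0.0405 for Cyp4a12a. Cyp4a12a and Cyp4a12b are paralogs whose probes may not tell them apart, and Cyp4a12b was at least 5.1-fold higher without passing. The adipokine gene Adipoq (2.45 ± 0.35) and Lhfpl3 (2.75 ± 0.35) did not pass either, nor did Ccn5 (at least 3.89-fold higher), Mrap (at least 2.98-fold) and Nlrp9c (at least 2.26-fold), each with both scramble siRNA arrays under 100. The other target of Nlrp9c was of the opposite sign, −0.26. The other 3 genes that rose carry clone or predicted names.

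The smallest absolute log2 change among the 94 genes was 2.78. At an unadjusted p under 0.05 there were 3435 genes in limma, 1565 higher and 1870 lower, where chance gives 1209. The groups did not overlap for 47.5% of genes, where chance gives 33.3%. With any 1 of the 4 arrays left out, no gene passed, with 2082 to 3342 genes at an unadjusted p under 0.05, and none passed with crossed replicate numbers as a block (3980 at an unadjusted p under 0.05). With a prior that follows intensity, 711 genes passed.

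**Figure D2:**
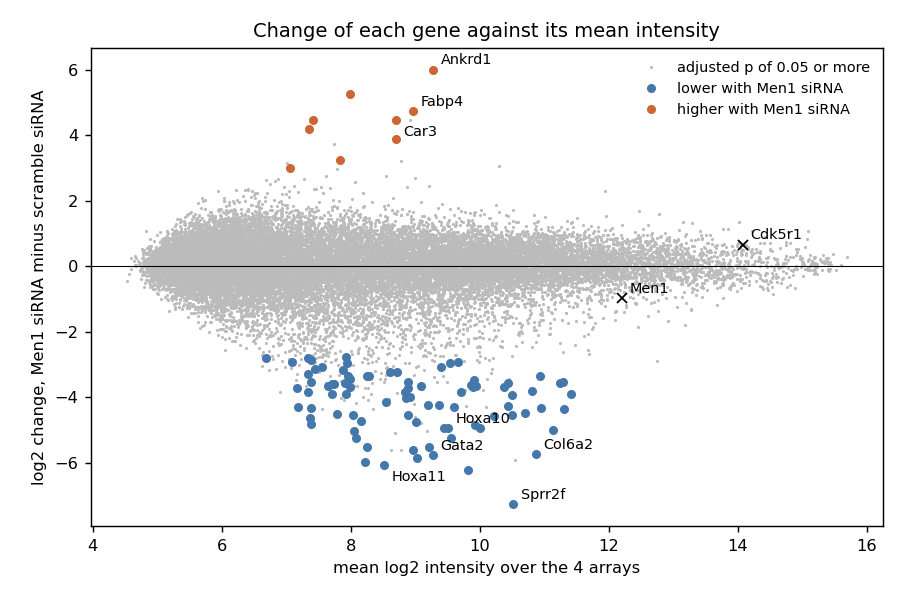
Log2 change (Men1 siRNA minus scramble siRNA) of each of 24171 genes against its mean log2 intensity over 4 arrays; coloured points are the 9 genes that rose and the 85 that fell, and crosses mark Men1 and Cdk5r1. The named decreases reach −7.28 (Sprr2f) and the fitted increases 6.01 (Ankrd1).

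Among markers of other cell types, camera at its preset correlation called the fibroblast list and the immune and endothelial list down. It did not call the glial list. Of 17 measured fibroblast and mesenchyme markers, 4 fell and none rose over all genes, and 10 fell and 2 rose adjusted over the list alone. Col1a1 and Col1a2, the chains of type I collagen, had log2 changes of −4.37 ± 0.34 and −3.57 ± 0.32, and Col6a1 fell by 4.57 ± 0.39. As the mean of its 3 targets Col1a2 had −1.46 without passing (adjusted p = 0.151). The list had a median log2 change of −1.55, and camera called it down (adjusted p = 5.87e-06). With an estimated correlation it did not pass (adjusted p = 0.264). Of 18 immune and endothelial markers, 0 passed over all genes, and 8 fell and 1 rose adjusted over the list alone. Values were −3.18 ± 0.38 for Cdh5 and −2.01 ± 0.30 for Kdr, both endothelial, and −2.23 ± 0.31 for Cd14 of myeloid cells. Endothelial Flt1, with both Men1 siRNA arrays under 100, was at least 4.79-fold lower without passing. The list median was −1.05 (camera adjusted p = 4.16e-05; adjusted p = 0.386 with an estimated correlation). Of 16 glial markers 0 passed, 12 were positive and the median was 0.39 (camera adjusted p = 0.192). Sox10 had −1.16 ± 0.35, Olig2 1.12 ± 0.34 and Mbp 1.08 ± 0.36.

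Hox genes, homeobox genes that pattern the body axis and are classical targets of the menin complex, were measured for 31 members. Over all genes 4 fell, 0 rose and 27 did not pass; adjusted over the list alone, 10 fell and 1 rose. Hoxa10 fell by 4.95 ± 0.30, from 4046 ± 175 to 131.2 ± 2.36 (mean ± SD, n = 2), and Hoxd9 fell by 4.03 ± 0.34, from 1883 to 116.7. Hoxb8 was at least 8.85-fold lower, and Hoxa11 is given above. The list median was −0.81 (camera adjusted p = 1.69e-05; adjusted p = 0.264 with an estimated correlation). Fibroblast markers had a median of −1.55 on the same arrays. Of 18 measured members of the menin and KMT2 methyltransferase complex, 0 passed. The methyltransferase genes Kmt2d and Kmt2a had −1.46 ± 0.35 and −0.59 ± 0.31, and the demethylase gene Kdm6a −0.86 ± 0.37. That list's median was −0.17 (camera adjusted p = 0.144). Of 15 cyclin-dependent kinase inhibitors and reported menin targets 0 passed, with a median of 0.35 (camera adjusted p = 0.215). Cdkn1b, which encodes p27, had 1.07 ± 0.32, and Cdkn2d 0.98 ± 0.35. Cdkn2a, with both scramble siRNA arrays under 100, was at least 1.73-fold higher without passing. Meis1, a Hox cofactor gene, had −1.16 ± 0.34.

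**Figure D3:**
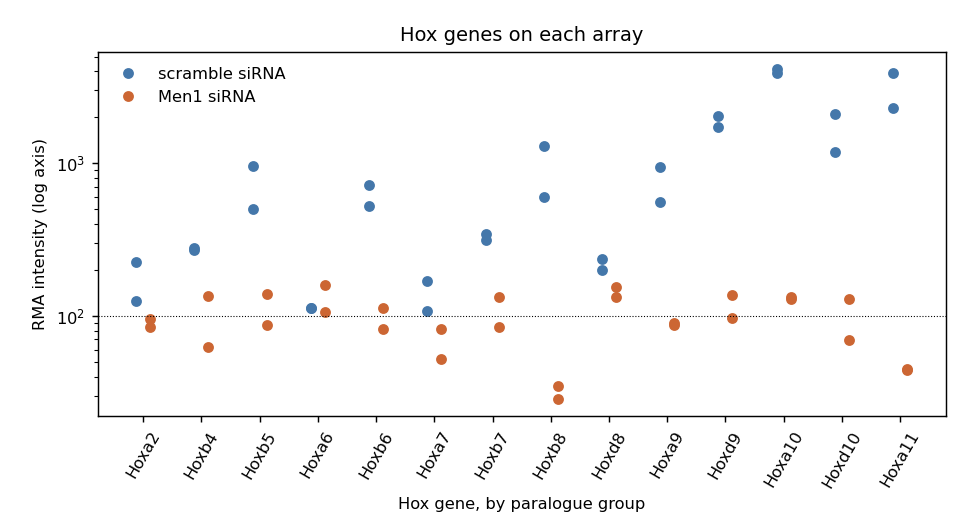
Intensity (log axis) on each array of the 14 Hox genes that reached 100 on both scramble siRNA arrays, ordered by paralogue group; the dotted line is at 100. Hoxa10 reads 4170 and 3922 with scramble siRNA against 129.5 and 132.9 with Men1 siRNA, whereas Hoxa6 has a log2 change of 0.22 (−0.07 without Men1 siRNA replicate 2).

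Interferon response genes were lower as a list. Of 32 measured, 1 fell over all genes, and 18 fell and 1 rose adjusted over the list alone. Irf7, the transcription factor gene that amplifies type I interferon, fell by 3.73 ± 0.37, from 1769 ± 591 to 129.7 ± 4.3 (mean ± SD, n = 2). The antiviral genes Oasl2, Xaf1 and Ifit1, with both Men1 siRNA arrays under 100, were at least 9.47-fold, 5.67-fold and 4.68-fold lower without passing. The median was −1.40 (camera adjusted p = 3.66e-12; adjusted p = 0.264 with an estimated correlation). Of 25 genes of NF-kB and the inflammatory response, 1 fell over all genes, and 4 fell and 1 rose adjusted over the list alone. Cd44, an adhesion receptor gene, was at least 6.87-fold lower at the brightest of its 4 targets, of which 2 were positive. It had −0.21 without scramble siRNA replicate 1 (adjusted p = 0.936), −1.76 without scramble siRNA replicate 2, −1.46 in the value table and −1.01 as the mean of its targets. Birc3 had −1.84 ± 0.31 and Csf1 1.67 ± 0.36. The median was −0.34 (camera adjusted p = 0.00702; adjusted p = 0.478 with an estimated correlation). Both lists moved with the immune and endothelial markers, whose median was −1.05.

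Signalling and growth lists were also lower. Of 36 genes of TGF-beta, BMP and Wnt signalling 0 passed over all genes and 6 fell adjusted over the list alone, with a median of −0.46 (camera adjusted p = 0.00013; adjusted p = 0.264 with an estimated correlation). Bmp7 had −2.75 ± 0.37, Tcf7 −2.13 ± 0.34, Fzd2 −2.37 ± 0.42 and Lrp5 −1.82 ± 0.34. Of 29 mitosis genes 0 passed, 23 were negative and the median was −0.74 (camera adjusted p = 0.000133; adjusted p = 0.386 with an estimated correlation). Top2a had −1.41 ± 0.34, Tpx2 −1.27 ± 0.33 and the proliferation marker Mki67 −1.13 ± 0.32. Of 54 ribosomal protein genes 0 passed, 47 were negative and the median was −0.35 (camera adjusted p = 0.000133; adjusted p = 0.264 with an estimated correlation). Rpl5 had −0.94 ± 0.37, Rps7 −0.76 ± 0.32 and Rps9 −0.67 ± 0.31. Of 32 genes of the hypoxia response and glycolysis 0 passed, with a median of −0.16 (camera adjusted p = 0.0447; adjusted p = 0.45 with an estimated correlation). Adm had −1.81 ± 0.46, Egln3 −1.89 ± 0.58, Hk2 −1.58 ± 0.54 and Vegfa −0.89 ± 0.31. Hk2 had −0.89 without scramble siRNA replicate 1. Egln3 had −1.24 without Men1 siRNA replicate 1 and −1.02 as the mean of its targets. Fibroblast markers, at a median of −1.55, moved the same way as these lists.

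Neuronal lists and a cholesterol list were higher, with no single member past the threshold. Of 30 genes of presynaptic vesicle release 28 were positive, with a median of 0.63 (camera adjusted p = 3.51e-05; adjusted p = 0.45 with an estimated correlation). The synapsin gene Syn3 had 1.41 ± 0.31 and Syt4 0.81 ± 0.31, whereas the vesicle protein gene Vamp1 had −1.03 ± 0.36. Of 32 genes of the postsynaptic density and its receptors 31 were positive, with a median of 0.47 (camera adjusted p = 0.000133; adjusted p = 0.264 with an estimated correlation). Shank1 had 1.31 ± 0.37 and the glutamate receptor gene Gria1 0.89 ± 0.33. Of 28 genes of the neurite and dendrite cytoskeleton 27 were positive, with a median of 0.40 (camera adjusted p = 0.00919; adjusted p = 0.478 with an estimated correlation). Ina had 0.82 ± 0.31, Map1b 0.72 ± 0.32 and Kif5a 0.79 ± 0.37. Of 25 genes of cholesterol biosynthesis and uptake 20 were positive, with a median of 0.34 (camera adjusted p = 0.026; adjusted p = 0.45 with an estimated correlation). Insig1 had 1.25 ± 0.33 and Mvd 0.76 ± 0.30. Glial markers had a median of 0.39 on the same arrays. The directions of the 13 lists that camera called held under cyclic loess, median and quantile normalization. Array medians were already close (145.9 to 151.2), so these alternatives could hardly turn a direction. In fry 0 of the 28 lists passed.

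The other 12 lists did not pass in camera. Of 36 axon guidance genes 0 passed over all genes and Sema5a (−2.79 ± 0.36) fell adjusted over the list alone, with a list median of 0.36 (camera adjusted p = 0.0643). As the mean of its 8 targets Sema5a had −0.47 (adjusted p = 0.498 over all genes). Epha3 had 1.70 ± 0.51 and Nrcam 1.00 ± 0.34. Of 37 genes of G1 to S phase and DNA replication 0 passed (median −0.27, camera adjusted p = 0.08); the helicase genes Mcm3 and Mcm2 had −1.44 ± 0.34 and −1.28 ± 0.30, and Ccnd2, which encodes cyclin D2, 1.39 ± 0.33. Cdc25a, a phosphatase gene of this list, read 89.8 and 82.2 on the scramble siRNA arrays and 235.7 and 197 on the Men1 siRNA arrays, without passing (adjusted p = 0.182). Its sign is not settled, with −0.43 and −0.39 without Men1 siRNA replicates 1 and 2 and −0.41 in the value table, where its other target stood for it. Of 22 sympathoadrenal and neuroblast genes, only Gata2 fell over all genes, 3 fell and 1 rose adjusted over the list alone, the median was 0.34 and the mean −0.13 (camera adjusted p = 0.499). Camera's direction for that list was up. Ret, a receptor gene of this lineage with both scramble siRNA arrays under 100, was at least 2.27-fold higher without passing, and Gata3 had −1.83 ± 0.40. In the list of Cdk5, its activators and partners (median 0.09, mean −0.12, camera adjusted p = 0.821, direction down) Nde1 and Capn1 had −2.22 ± 0.40 and −2.08 ± 0.44 and fell adjusted over the list alone. Cdk5r2, the p39 activator gene, had 0.96 ± 0.32 and Cdk5 0.76 ± 0.35.

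Of 25 p53 targets 0 passed over all genes (median 0.30, camera adjusted p = 0.391); Gadd45a had −1.90 ± 0.33 and fell adjusted over the list alone, and Gdf15 had 2.56 ± 0.66. Of 26 apoptosis regulators 0 passed (median −0.03, camera adjusted p = 0.5), with 1.61 ± 0.30 for Apaf1. Of 25 Notch and neural progenitor factors 0 passed (median 0.26, mean −0.02, camera adjusted p = 0.546, direction up), with −2.97 ± 0.74 for Dll4, −1.90 ± 0.60 for Hes1 and 0.84 ± 0.30 for Nes. With 1 array left out these came as near 0 as −1.84 for Dll4, −1.03 for Hes1 and 0.25 for Nes. Of 27 immediate early genes 0 passed (median −0.03, camera adjusted p = 0.415), with −2.08 ± 0.38 for Klf4 and −1.43 ± 0.49 for Junb. Of 30 genes of the unfolded protein and integrated stress response 0 passed (median −0.06, mean 0.02, camera adjusted p = 0.821, direction down), with 1.19 ± 0.32 for Vldlr and 1.21 ± 0.37 for Chac1. Without Men1 siRNA replicate 2 Vldlr had 0.40. Of 45 oxidative phosphorylation genes 0 passed (median 0.19, camera adjusted p = 0.203), with 1.23 ± 0.31 for Cox7b. Of 13 small RNA pathway genes 0 passed (median 0.30, camera adjusted p = 0.192), with 0.79 ± 0.37 for Ago2. Of 16 housekeeping genes 0 passed over all genes (median −0.16, camera adjusted p = 0.204), with −0.66 ± 0.33 for Polr2a and −1.67 ± 0.30 for Gusb, which fell adjusted over the list alone. In the lists without such a count, 0 members passed adjusted over the list alone.

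**Figure D4:**
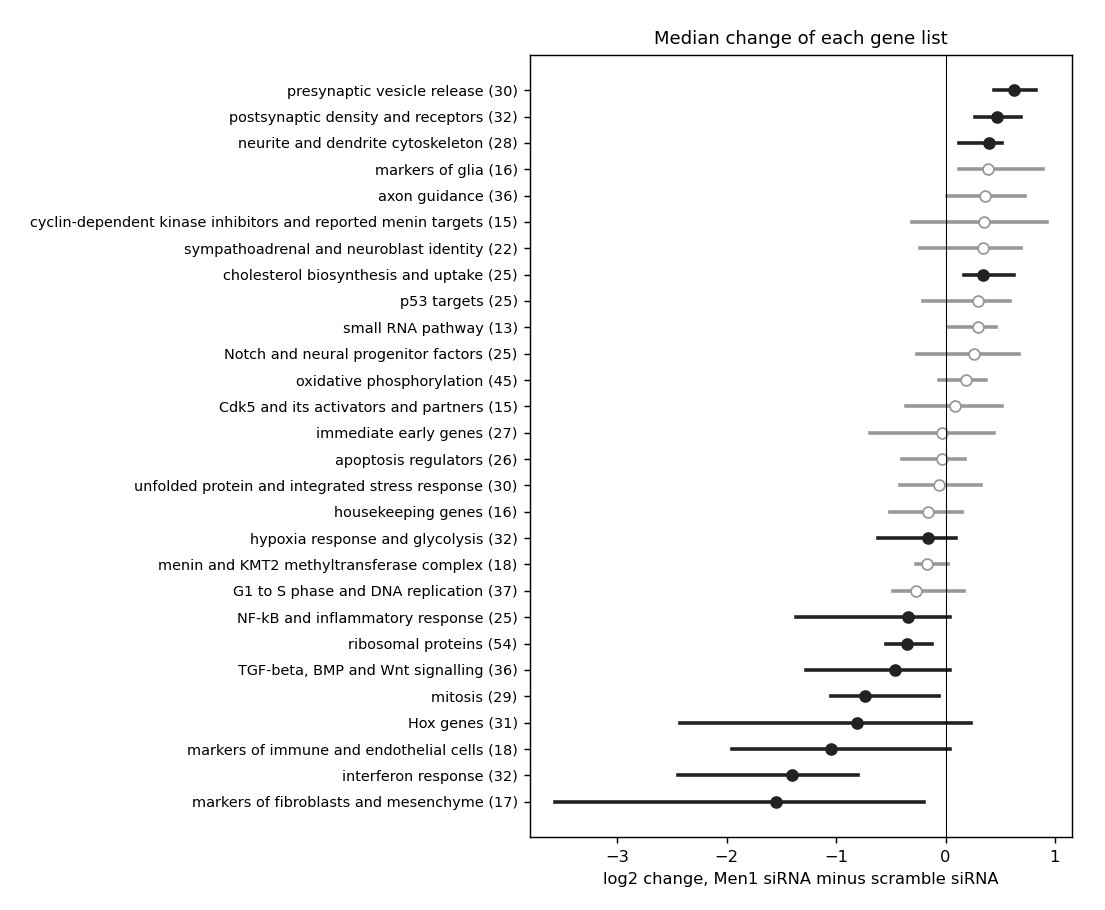
Median log2 change (Men1 siRNA minus scramble siRNA, point) and quartiles (bar) of the members of each of 28 gene lists, with the number measured in brackets; filled points are the 13 lists that camera called at its preset correlation. Medians run from −1.55 (fibroblast and mesenchyme markers) to 0.63 (presynaptic vesicle release).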

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

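The crossed replicate block and the floor at 100 were chosen after the data were seen. Men1 kept its sign in all 15 alternatives, with log2 changes from −1.25 to −0.58, and passed in none. Of the 94 genes called, 93 kept their direction in every alternative that tested them. That is no separate support, because the 94 were picked on these arrays and each had an absolute log2 change of at least 2.78. The exception, Slc39a8, went from a fitted −4.34 to 1.09 without scramble siRNA replicate 1, where another of its 4 targets had the highest mean. With the replicate number as a block, 69 genes passed, 62 of them among the 94. The correlation of the replicate differences of the 2 groups was −0.17 as numbered. Crossing the scramble siRNA numbers only turns its sign, to 0.17, which is no separate observation. With crossed numbers as the block no gene passed (0 in limma, 3980 at an unadjusted p under 0.05), and the cause was not tested; the value table exchanges the 2 scramble siRNA columns, so the replicate numbers may be crossed. Leaving out scramble siRNA replicate 1 or 2, or Men1 siRNA replicate 1 or 2, gave 0 to 0 genes, with 2082, 3342, 3167 and 2581 genes at an unadjusted p under 0.05; fewer arrays leave a single residual comparison, and the lone array of a group is assumed to vary like the other group. Lists called were then 9 to 15. Under an adjusted p of 0.01, 0 genes passed (3435 at an unadjusted p under 0.05). More genes passed with a trended prior (711, of which 588 fell), genes above the median only (576, 503 fell), the value table (418, 364 fell), log2(value + 32) (256, 239 fell) and each target alone (150, 138 fell, among 44170 targets). The filter and the value table test fewer genes, 12085 and 12701, and the other causes were not tested. The floor of 100 gave 27 genes, 3 of them among the 94, and made the variance of some genes 0, and the cause was not tested. Of the 28 lists, 0 passed with an estimated correlation (4 at an unadjusted p under 0.05) and 0 in fry (10, of which 9 are among the 13 that camera called; lowest adjusted p 0.0632). A robust prior was not run for lists, which camera does not use. Besides Men1, 87 genes are given with a log2 change or bound and were not called; 38 of them moved by over 1.5 times in at least 1 alternative, 22 as the mean of all targets and 17 with an array left out. Hoxa6 was reversed without Men1 siRNA replicate 2 (−0.07 against 0.22; 0.52 without Men1 siRNA replicate 1). Cdc25a, fitted at 1.33, was reversed without Men1 siRNA replicate 1 (−0.43), without Men1 siRNA replicate 2 (−0.39) and in the value table (−0.41), where its other target stood for it, with up to 1.39 when a scramble siRNA array was left out. Cdk5r1 was reversed in the value table, −0.66 against 0.66, because that table holds the other group's values for its 3 targets; over its 15 alternatives limma's adjusted p ran from 0.128 to 0.747. Intensities under 100 limit the rest: 38 of the 85 genes that fell have only a bound.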

Other observations

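Some tests in this part were chosen after their results were seen. These were the tests of whole value table columns, of Hox genes as the whole cause and of the other splits of the arrays. Those of Hox genes at any level and by their mean over the arrays were too. All whole-tissue marker lists were written after the leading genes had been looked at, and before the markers they call new had been read.

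Among genes of epithelia chosen after their values were seen, Krt18 and Krt8, keratin genes, had log2 changes of −4.48 ± 0.43 and −3.67 ± 0.32, and Cdh1, which encodes E-cadherin, −4.56 ± 0.42 (SE, n = 2 per group). Muc1, a mucin gene, had −4.14 ± 0.45, the lactoferrin gene Ltf −3.23 ± 0.35 and Sox17 −4.95 ± 0.45, and all 6 passed the threshold in limma. Epcam (−3.43 ± 0.69), Krt19 (−3.31 ± 0.42) and the oestrogen receptor gene Esr1 (−2.21 ± 0.33) did not pass. Of the epithelial markers listed before they were read, Cldn7 (−4.62 ± 0.72), Elf3 (−3.36 ± 0.58) and Klf5 (−1.47 ± 0.45) did not pass, nor did Slpi, which had the opposite sign (0.86 ± 0.36). On the scramble siRNA arrays Krt18 read 9975 and 6196, and on the Men1 siRNA arrays 269.5 and 457.5. Limma's adjusted p was 0.0364 for Krt18 and 0.0347 for Cdh1. Of adipose markers, Fabp4 and Car3 passed, and the lipoprotein lipase gene Lpl (1.89 ± 0.30) and Cidec (2.96 ± 0.47) had positive values without passing. Lpl had 0.50 as the mean of its targets, and Cidec had 4.86 without scramble siRNA replicate 2. The 13 adipose markers not read before had a median log2 change of 0.78 and 15 kidney markers 0.46, against up to 0.72 in 11 lists of other tissues.

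The genes that fell and the posterior Hox genes form a pattern. Hox genes account for 4.7% of the 85 genes that fell, which decides nothing on Hox transcription after loss of menin as the whole cause, since only 31 were measured and genes downstream of them are not counted. A candidate explanation is RNA of the female reproductive tract on the scramble siRNA arrays. For it, 20 markers not read before had a median of −1.88, 19 of them negative. In 11 lists of other tissues medians were −0.22 to 0.72. That contrast cannot decide, because 19 of the 20 markers reached 100 on both scramble siRNA arrays. In the other lists 0 of 7 (placenta) to 5 of 11 (skeletal muscle) did, and genes near background have little room to fall. Brighter lists went both ways. Forebrain markers had medians of 0.49 (cortical) and 0.54 (GABAergic). Of these, 13 of 14 and 11 of 11 reached 100 on both scramble siRNA arrays. Fibroblast markers, 14 of 17 at 100 or more on all 4 arrays, had −1.55. Room to fall thus gave no decrease by itself, and a decrease was not particular to reproductive tract markers. Without the 2 markers that passed the test and were already among the leading genes, the other 18 had a median of −1.54. Several markers are general epithelial genes, so another epithelium stays open, and none is in the 28 lists. For Hox genes both explanations stay open. Asking for 100 or more on both scramble siRNA arrays favours decreases. At that level 7 posterior ones had a median of −4.07 and 3 anterior ones −1.57. All 15 and 11 measured had −0.60 and −0.76, but these include genes near background, which have little room to fall. With a mean of 100 or more over the 4 arrays, 7 posterior ones had a median of −4.07, all 7 negative. By that filter 5 anterior ones had −0.90, with 3 negative. Tissue RNA and the siRNA follow the same 2 groups.

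The opposite order of Cdk5r1 in the 2 deposited sources forms a second pattern. An exchange of whole columns between the groups in the value table is argued against by the 20617 of 20620 targets whose values equal arrays of the same group. The 3 targets that differ all belong to 1 gene. Whether the entries of this gene were exchanged in the value table or in the per-array files stays open, and neither source alone settles the direction of Cdk5r1. No biological explanation was tested, since both sources record the same arrays.

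Transcripts of brain tissue on all 4 arrays form a further pattern: of 25 forebrain neuron markers not read before, 2 of them in the 28 lists, 92% reached 100 on all 4 arrays, against at most 42.9% (lung) in 11 comparison lists, 53.8% of adipose and 65% of reproductive tract markers not read before, and 52.3% of all genes. Their median log2 changes were 0.49 (cortical, 13 of 14 positive) and 0.54 (GABAergic, 10 of 11 positive), the direction of the neuronal lists (0.40 to 0.63) and within the range of the 11 lists (−0.22 to 0.72), and what moved them was not tested. RNA of forebrain tissue is a candidate source, but no reference of N2a cells was used here to say how many of these genes the line expresses itself, and no biological explanation was tested. Calb2 read 7068 to 16930, Neurod2 4894 to 9423, Dlx1 4190 to 7355 and Tbr1 1450 to 3150. For blood, the globin genes Hbb-b1 and Hba-a2 read 7273 to 23470 and 10150 to 20550, but 25% of 8 other red cell markers reached 100, too few to decide.

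Xist, expressed from the inactive X chromosome, read 922.4 to 1818 over the 4 arrays, and the Y-linked gene Eif2s3y 384.5 to 705.9. Of other Y-linked genes, Kdm5d read 148 to 254.4 and Ddx3y 109.9 to 329. Uty, at 41.4 to 78.6, stayed under 100 on all 4 arrays. Xist and Y-linked genes were thus read on the same arrays. Whether the RNA came from N2a cells alone was not tested and stays open. Of the 85 genes that fell, 69 were higher in scramble siRNA replicate 1 than in replicate 2, with a median log2 difference of 0.35 (SD 0.48), against −0.08 (SD 0.73) over all 24171 genes, of which 10777 were higher in replicate 1. The 4 arrays allow 3 splits into 2 and 2, too few for a share under 0.05. Only 1 split of the 3, the labels' own, gave 94 genes. Both others gave 0 in limma, with 347 and 952 genes at an unadjusted p under 0.05, where chance gives 1209. Those 2 splits leave the difference between the labelled groups in the residual spread. They were therefore bound to call few genes and decide nothing.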
